A study of Mus musculus with 7 samples.

How the data were processed

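Total RNA from the apex of 7 mouse hearts (4 controls, 3 KO) was hybridised to 1-colour Agilent arrays, 100 ng RNA per labelling reaction, per the labels. The labels name separate hearts, taken here as separate animals. The study's design text speaks of 4 KO hearts; the other one was not analysed here. Groups were taken from the titles.

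Per the file headers, the authors scanned the arrays and read them with Agilent Feature Extraction 11.0.1.1, and the deposited scanner files hold the intensity of 62976 spots per array, of which 3671 were control spots. The intensity used was the background-subtracted processed signal of the software, per the file headers. The same files hold the median spot and background intensity and flags for saturation, outliers and signal well above background. The design carries the mm9 genome build, per the file headers; no coordinates are given, since the gene table used for names is of GRCm38. The deposited value table of the series holds log2 values, with scale, centring and direction not stated. Set against the scanner values, its columns correlated with median-centred log2 signals at 0.986 to 0.998 with slopes from 0.962 to 1.01 over 15000 bright probes, and 100% of its rows had a median of 0, so each probe was centred on its median over the 7 arrays and higher values mean more signal; which percentile or target set the scale stays unknown. Column medians were 0 for control 1, 2 and 3, KO 1 and KO 3, 0.00793 for control 4 and -0.00210 for KO 2.

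Processed signals were turned to log2 and each array's 75th percentile over non-control spots was subtracted. Control spots and spots marked as outliers were left out, saturated spots were kept, and spots of 1 probe were averaged. The median coefficient of variation of replicated probes, as the software gave it, was 4.52% to 5.38% per array. Probes were kept if well above background on at least 3 arrays of at least 1 group (26576 of 55681). Probes were named through the RefSeq accession in the files: 28026 matched 1 symbol, 27655 none and 0 several. Probes with no match were tested under their probe name and are not named here. For each gene the kept probe with the highest mean over all arrays was used; of 3535 genes with several kept probes, 13 had probes called in opposite directions, Mef2a and Brix1 among them. This left 22344 features, 13697 of them named genes; 42 with a missing value were left out of list tests and correlations.

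KO was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Log2 differences are KO minus control, with the standard error of the fit. In counts of list members, those said to rise or fall are those that passed the threshold. A gene whose probes were not well above background on any array of a group has only a bound there: the brighter group's mean was set against the mean of, per array, the higher of the gene's own signal and the lowest signal among probes well above background, and is given as at least N-fold. A total of 33 gene lists were fixed before the data were examined, of which 32 (pathways and cell type markers) were tested and the other held the label checks. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. List means per heart (mean of gene-centred log2 values) were compared by an exact two-sided permutation test over the 35 splits of 7 hearts into 4 and 3, where the smallest possible p is 0.0286. Named genes followed a rule fixed at the same time: the p38 genes, the 15 largest rises and 15 largest falls among named genes that passed without overlap between groups (1608 and 2012 were eligible; clone and predicted gene names were left out), up to 4 members with the lowest p per list, and the label checks. Some genes that the rule selects are not reported here.

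On simulated data with 22302 features and the arrays' own spread, the gene test recovered 2.0%, 30.0%, 80.0% and 92.0% of 50 genes each changed by 0.5, 1, 2 and 3 on the log2 scale, with 2 false among 104 calls, and camera called a list of 40 genes raised by 0.5 and 0 of 19 unchanged lists. Simulated genes were independent of one another and few changed. In the data 5640 features passed, and the estimated correlation within the oxidative phosphorylation list was 0.871. These rates therefore need not hold for the data, and the simulation could not show false list calls that arise where genes move together.

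The alternatives fixed before the data were examined were normexp background correction (offset 50), quantile normalization, median centring, no filter, a filter on all arrays, the authors' value table, means over probes, trend and robust variance, array weights, replicate number or slide row as a block, each heart left out, an unmoderated test and a threshold of 0.1. The scanner files hold no mean spot signal, so normexp used the median spot signal. All arrays were on 1 slide with 1 scan time, so the row on the slide took the place of the slide. Analyses within a slide row, a 75th percentile over detected probes (since under 50.0% of probes were well above background), removal of hepatocyte markers and 4 further gene lists were chosen after seeing the data. The p values of these 4 lists were adjusted among themselves, apart from the lists fixed before.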

Results

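Gene expression was measured in the apex of the heart of 7 male C57BL/6 mice on 1-colour Agilent microarrays. All animals carried a floxed Mapk14 gene, which encodes the stress-activated kinase p38α, with exons 2 and 3 between loxP sites. The 3 knockout (KO) animals also carried MerCreMer, a tamoxifen-activated Cre recombinase, under the cardiomyocyte α-MHC promoter, and the 4 controls did not. Both groups received 500 µg hydroxytamoxifen per day for 10 days from the age of 6 weeks, and angiotensin II, a pressor peptide, at 1.5 mg/kg per day from osmotic minipumps for 48 hours before tissue was taken at 3 months. The comparison asks how loss of p38α in cardiomyocytes changes cardiac gene expression under angiotensin II. Since the Cre transgene was present in the KO group only, deletion and Cre cannot be told apart in it. All 7 arrays lay on 1 slide, and 46.0% to 49.7% of the 55681 probes were well above background on each. The number of arrays, 4 against 3, limits the precision of every value.

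Mapk14 itself did not differ past the threshold between KO and control hearts. Its brighter probe read 3.51 ± 0.11 (SD, n = 4) in controls and 3.74 ± 0.03 (SD, n = 3) in KO hearts on the log2 scale relative to the array's 75th percentile, a difference of 0.22 ± 0.12 (SE) with an adjusted p of 0.202. The dimmer probe differed by 0.18, with an exact two-sided permutation p of 0.143 against 0.0571 for the brighter. Where these probes lie in the transcript was not given in the sources used here. A probe outside exons 2 and 3, or transcript from cells other than cardiomyocytes, need not report the deletion. The lack of a fall in Mapk14 therefore does not decide whether the labels hold. The other p38 genes did not pass either: the log2 differences were 0.28 for Mapk11 (adjusted p = 0.247), 0.17 for Mapk12 (0.457) and -0.20 for Mapk13 (0.767).

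Esr1, the oestrogen receptor gene whose ligand-binding part is contained in MerCreMer, separated the groups as the labels do. One of its probes was not well above background on any of the 4 control arrays and was well above it on all 3 KO arrays, at log2 levels of -0.82, 0.07 and 4.50, at least 40.7-fold higher in KO (adjusted p = 0.0123). The bound rested on single KO hearts, at 13.2-fold without KO replicate 3 and 83.5-fold without KO replicate 1, and did not hold with normexp background correction, where the difference was 15.3-fold. The other Esr1 probes were not well above background on any array. Xist, transcribed from the inactive X chromosome of females, was not well above background on any array, while the Y-linked genes Ddx3y and Eif2s3y were well above it on all 7. Of the other Y-linked genes, Kdm5d was not well above background on any array, and the probes of Uty were well above it on all 4 control arrays, and on 2 of the 3 KO arrays for the brighter and 1 for the dimmer.

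Gene expression differed widely between KO and control hearts. Of 22344 genes and unnamed probes tested, 5640 passed an adjusted p of 0.05, 2284 higher and 3356 lower in KO, and 2302 of them changed at least 2-fold (910 higher, 1392 lower). Among the 13697 named genes 3875 passed, 1691 higher and 2184 lower. Over the 13673 named genes with a value on every array, passed or not, the groups did not overlap in 5775 (42.2%). Chance gives 5.71% on average, but genes move together, so how far a chance share can lie from that was not measured. The count rested on single hearts: it was 69 without KO replicate 1, 1138 without KO replicate 2, 2217 without control replicate 4, 2699 without control replicate 3 and 3266 without control replicate 1. It was 90 with an unmoderated test per gene and 1415 with no filter on dim probes.

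Arg1, Chil3 and Gdf15 were among the largest rises by fitted difference. Arg1, which encodes the macrophage enzyme arginase, was higher in KO by a log2 difference of 5.86 ± 1.34 (SE, adjusted p = 0.0216), which is 58.2-fold, 33.2-fold without control replicate 3, 121-fold without control replicate 2 and 13.8-fold with normexp background correction. The chitinase-like gene Chil3 rose by 5.05, or 4.18 without control replicate 4 and 5.80 without KO replicate 3, and Chil4 was at least 3.10-fold higher, or 1.90-fold without KO replicate 2 and 5.20-fold without KO replicate 3. Gdf15, a stress-induced cytokine of the TGFβ family, rose by 3.74 ± 0.77 (SE, adjusted p = 0.0176), or 4.46 without control replicate 2. The decoy interleukin-1 receptor Il1r2 rose by 4.26, the acute phase gene Saa3 by 4.09 and the C-type lectin receptor Clec4e by 3.77 on the log2 scale, or by 2.04, 2.60 and 2.23 with normexp. Sprr2g, Mogat2, Prss46, Crct1, Steap1, AA467197 and Pak3 completed the 15 largest fitted rises, with log2 differences from 3.81 to 5.57. Arg1, Mogat2, Crct1 and Steap1 were well above background on 2 of the 4 control arrays, and Sprr2g, Il1r2 and Prss46 on 1 of 4, so these differences rest partly on control values near background. Leaving out 1 heart moved the fold or bound of each of the 15 by over 1.5 times: control replicate 2 did so for 9 genes, control replicate 4 for 8, KO replicate 3 for 5, KO replicate 2 for 4, control replicate 3 for 2 and KO replicate 1 for 1. With normexp 12 of the 15 were smaller by over 1.5 times, and Chil4, at 2.21-fold, lay below its bound.

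Transcripts best known from liver were prominent among the 15 largest falls by fitted difference, 9 of which have only a bound, so their rank by size is not known. Saa2 was at least 12.2-fold lower in KO (adjusted p = 0.00338), Alb, which encodes albumin, at least 9.90-fold lower (adjusted p = 0.00203) and the major urinary protein gene Mup19 at least 7.61-fold lower (adjusted p = 0.00338), each well above background on all 4 control arrays and on no KO array. Mup18, Fabp1, Kng1, Fgg and Mup17 showed the same pattern of detection, at least 4.19-, 3.29-, 5.87-, 2.86- and 2.60-fold lower, while Serpina1a fell by 3.77 on the log2 scale and was detected on all 7 arrays. These bounds hold for the background-subtracted signal: with normexp the log2 differences were -2.19 for Saa2, -1.89 for Alb and -1.56 for Mup19, nearer 0 than the bounds and still called, and -1.40 to -1.03 for Mup18, Fabp1, Kng1, Fgg and Mup17. Kcnip2, which encodes the KChIP2 subunit of the transient outward potassium channel, fell by 4.11 ± 0.57 (SE, log2, adjusted p = 0.0118), from 0.88 ± 0.90 (SD, n = 4) to -3.23 ± 0.95 (SD, n = 3). Armc2, Tmprss13 and Grhl2 fell by 4.25, 4.70 and 4.01 on the log2 scale, or 5.28, 5.98 and 5.05 without KO replicate 3. Slc9a3 was 16.0-fold lower, or 29.2-fold without KO replicate 3, and Hs3st5 was at least 4.72-fold lower. Without KO replicate 1 Armc2 was at -3.63 and without KO replicate 2 Tmprss13 at -3.98. Tmprss13, Grhl2 and Slc9a3 were well above background on 1 of the 3 KO arrays and Kcnip2 on 2, so these differences rest partly on KO values near background. With normexp 13 of the 15 falls were smaller by over 1.5 times: Kcnip2 fell by 2.79, Serpina1a by 2.52, Armc2 by 3.58, Tmprss13 by 2.19, Slc9a3 by 1.95 and Hs3st5 by 1.34, the last less than its bound, and Grhl2 was 3.04-fold lower.

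**Figure D1:**
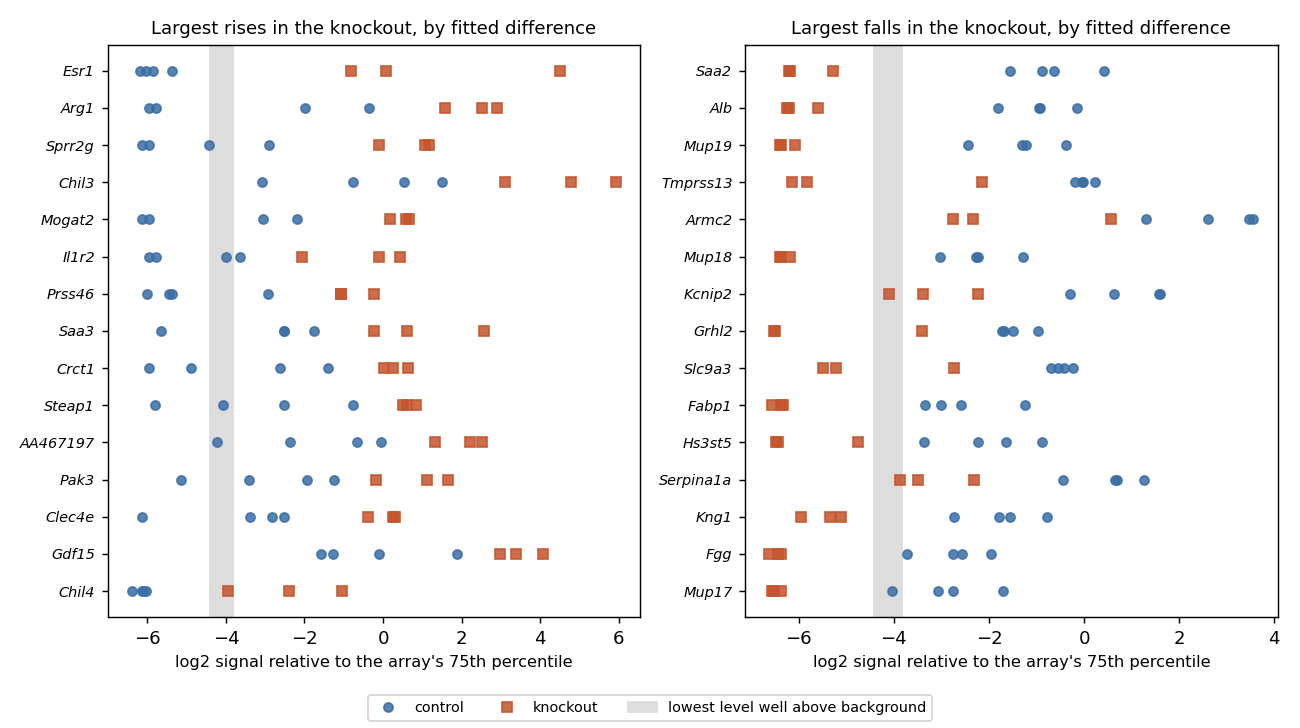
Log2 signal relative to each array's 75th percentile (x axis) of the 15 genes with the largest rises (left) and the 15 with the largest falls (right) by fitted difference, those with only a bound included, 1 symbol per array for 4 control and 3 KO hearts; the grey band spans the lowest level well above background on the 7 arrays. Albumin (Alb) and the Mup genes lay left of the band on every KO array and, except Mup17 in 1 control, right of it on every control array.

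Genes of mitochondrial energy production were lower in KO almost without exception. Of 54 measured genes of oxidative phosphorylation and the citrate cycle 51 fell and 0 rose, with a median log2 difference of -0.79 (camera adjusted p = 8.42e-16), and 54 fell when adjusted over the list alone. With an estimated correlation between genes in place of the preset 0.01, this list and those of fatty acid oxidation and branched-chain amino acid breakdown had an adjusted p = 0.45. Cycs, which encodes cytochrome c, fell by 1.01 ± 0.15 (SE, log2, adjusted p = 0.0123), Idh3a of the citrate cycle by 1.19 ± 0.18, and the complex I genes Ndufa8 and Ndufa5 by 0.96 and 0.89. Of 28 fatty acid oxidation genes 26 fell and 0 rose (median -0.86, camera adjusted p = 1.98e-09; 27 adjusted over the list alone). Cpt1b, the muscle carnitine palmitoyltransferase that admits fatty acids to mitochondria, fell by 1.18 ± 0.19 (adjusted p = 0.0125), Acsl1 by 1.62 and Cpt2 by 1.29. Of 20 genes of branched-chain amino acid breakdown 14 fell and 0 rose (median -0.97, camera adjusted p = 5.60e-06; 17 adjusted over the list alone), with Hibch at -1.30 and Acad8 at -1.32.

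Genes of lipid and glucose handling moved in both directions, with more falls. Of 42 genes of lipid uptake, storage and PPAR targets 18 fell and 4 rose (median -0.74, camera adjusted p = 0.00307; 21 and 5 adjusted over the list alone). Esrrb, a nuclear receptor, fell by 1.65 ± 0.23 (SE, log2, adjusted p = 0.0118), and Acacb, which makes the malonyl-CoA that restrains Cpt1b, by 1.50 ± 0.21. Of 33 genes of glucose uptake and glycolysis 15 fell and 5 rose (median -0.39, camera adjusted p = 0.0271; 17 and 6 adjusted over the list alone). Slc2a4, which encodes the insulin-responsive glucose transporter GLUT4, fell by 2.71 ± 0.42 (adjusted p = 0.0123), Pfkl and Gys1 by 1.17 and 1.18, while G6pdx of the pentose phosphate pathway rose by 1.22. The glycolysis call did not hold with quantile normalization (adjusted p = 0.0577), in the authors' value table (0.0515) or without control replicate 1 (0.0525), and both lists had an adjusted p = 0.45 with an estimated correlation.

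Those contractile and excitation genes of cardiomyocytes that passed over all features were also lower, while 11 contractile and 12 excitation genes did not pass. Of 25 contractile genes 14 fell and 0 rose (median -0.73, camera adjusted p = 5.40e-07; 18 adjusted over the list alone). Tcap, the titin cap, fell by 1.70 ± 0.20 (SE, log2, adjusted p = 0.0103), cardiac troponin I (Tnni3) by 1.19 ± 0.20, Mybpc3 by 1.22 and Ldb3 by 0.87. Of 31 genes of calcium handling, ion channels and gap junctions 19 fell and 0 rose (median -0.82, camera adjusted p = 5.63e-06; adjusted over the list alone 22 fell and 2 rose). Besides Kcnip2, the potassium channel genes Kcnj11 and Kcnj5 fell by 2.20 ± 0.33 and 0.90 ± 0.12, and Casq2, the calcium buffer of the sarcoplasmic reticulum, by 0.88 ± 0.14. Both lists had an adjusted p = 0.45 with an estimated correlation.

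Among genes of the cardiac stress programme, of the integrated stress response, of the immediate early response and of cell death, more rose than fell. Of 24 cardiac stress and fetal genes 9 rose and 2 fell (median 0.81, camera adjusted p = 0.000143; 12 and 2 adjusted over the list alone). The metallothionein gene Mt2 rose by 1.68 ± 0.34 and the calcineurin regulator Rcan1 by 1.01 ± 0.20 (SE, log2), and the myosin gene Myh7b fell by 1.86 ± 0.28. The natriuretic peptide genes Nppa and Nppb of this list were not among those that rose. Of 32 genes of the integrated stress and unfolded protein responses 11 rose and 2 fell (median 0.66, camera adjusted p = 0.000143; 12 and 2 adjusted over the list alone). The serine and one-carbon enzymes Psat1 and Mthfd2 rose by 2.43 ± 0.46 and 2.18 ± 0.38, and the amino acid transporter subunit Slc3a2 by 0.93. Of 30 immediate early genes 11 rose and 1 fell (median 1.03, camera adjusted p = 4.12e-06; 16 and 1 adjusted over the list alone). Gadd45g rose by 2.51 ± 0.48 and Fosl2 by 1.23. Fosl1, well above background on 1 of the 4 control arrays, rose by 3.48 ± 0.64, or 4.14 without KO replicate 3, while Nr4a3 was at least 1.59-fold lower. Of 29 genes of cell death and p53 targets 13 rose and 4 fell (median 0.70, camera adjusted p = 0.00307; 16 and 5 adjusted over the list alone). The pro-apoptotic genes Bid, Pmaip1 and Bax rose by 1.32 ± 0.21, 1.47 ± 0.23 and 0.78 ± 0.15, and the kinase gene Ripk1 by 0.88 ± 0.13. Each of these lists had an adjusted p = 0.45 with an estimated correlation. In the authors' value table Pmaip1 was -0.73 and did not pass (adjusted p = 0.811).

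Those markers of innate immune cells and inflammatory mediators that passed were all higher in KO. Of the neutrophil markers 5 did not pass, of the monocyte and macrophage markers 17, and of the cytokines, chemokines and adhesion molecules 19. The lowest members of these lists were at -0.24, -0.56 and -0.47. Of 14 neutrophil markers 9 rose (median 2.88, or 1.86 with members not well above background in controls set at their bound, camera adjusted p = 5.63e-06; 11 adjusted over the list alone). With normexp background correction the median was 1.37. The formyl peptide receptor genes Fpr2 and Fpr1, each well above background on 2 of the 4 control arrays, rose by 3.04 ± 0.29 (SE, log2, adjusted p = 0.00522) and 3.45 ± 0.52 (0.0123), or 1.38 and 1.89 with normexp, and the gelatinase gene Mmp9 was at least 2.40-fold higher (0.00958). Of 28 monocyte and macrophage markers 11 rose (median 0.997, camera adjusted p = 1.30e-06; 17 adjusted over the list alone). The lipopolysaccharide co-receptor gene Cd14 rose by 1.43 ± 0.24, the scavenger receptor Msr1 by 2.34 ± 0.47 and the Fc receptor Fcgr1 by 1.67 ± 0.35. Of 32 cytokines, chemokines and adhesion molecules 13 rose (median 1.33, camera adjusted p = 5.49e-07; 16 adjusted over the list alone). The chemokine genes Ccl6 and Ccl9 rose by 2.05 ± 0.30 and 1.90 ± 0.35, Il1b by 2.02 ± 0.46 and Csf1 by 0.84 ± 0.18. With an estimated correlation each list had an adjusted p = 0.45. Of 29 interferon response genes 0 passed (median -0.02, camera adjusted p = 0.699), with Rsad2 at -0.72 (adjusted p = 0.0543) and Psmb8 at 0.52 (0.0557, or 0.0324 with normexp). The KO hearts differed, with list means of -0.49, 0.42 and 0.04 in KO 1 to 3, and without KO replicate 1 the list passed (median 0.23, adjusted p = 0.018).

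Those matrix genes that passed were higher in KO, while markers of resident cell types moved in different directions. Of 47 genes of extracellular matrix and fibrosis 11 rose and 0 fell (median 0.72, camera adjusted p = 1.01e-05; 13 adjusted over the list alone; adjusted p = 0.45 with an estimated correlation), and 36 did not pass. The list means of the hearts overlapped between the groups (exact permutation p = 0.114), and without control replicate 2 the median was 1.11. The stromelysin gene Mmp3 rose by 2.48 ± 0.41 (SE, log2, adjusted p = 0.0125) and Tgfb2 by 2.36 ± 0.34. Of 15 fibroblast markers 5 fell and 1 rose (median -0.71, camera adjusted p = 0.109; 7 and 1 adjusted over the list alone). The fibroblast list passed with replicate number as a block (median -0.66, adjusted p = 0.037), without control replicate 3 (-0.59, 0.0498) and without KO replicate 3 (-0.84, 0.00635). Clec3b fell by 2.43, or 1.78 without KO replicate 2 and 3.20 without KO replicate 3, Pi16 by 1.27 and Htra3 by 1.23, and Pdgfra rose by 0.68 ± 0.14. Among 18 endothelial markers Kdr, the main VEGF receptor, fell by 1.20 ± 0.19 and Plvap rose by 0.50, and 16 did not pass (median -0.24, camera adjusted p = 0.243; 1 fell and 0 rose adjusted over the list alone). Of 12 smooth muscle and pericyte markers 3 fell, Smtn, Abcc9 and Rgs5 (median -0.18, camera adjusted p = 0.338; 3 adjusted over the list alone). Of 9 lymphocyte markers 1 rose, Il7r, at least 1.96-fold (median 0.28, camera adjusted p = 0.223; 1 adjusted over the list alone). Of 7 nerve and mesothelial markers 3 rose, Krt19, Msln and Mbp (median 0.32, camera adjusted p = 0.223; 3 adjusted over the list alone), and their list mean was higher in each KO heart than in any control (exact permutation p = 0.0286). The median of this list was 0.07 without KO replicate 2 and 0.73 without KO replicate 3. Of 8 erythroid markers 6 fell, haemoglobin genes among them (Hbb-bt by 0.93, Hba-a1 by 0.74, camera adjusted p = 0.00307; 7 adjusted over the list alone). Of 5 adipocyte markers 3 fell, Cidea, Car3 and Aqp7 (camera adjusted p = 0.0188; 3 adjusted over the list alone), of which Car3 lost its call with normexp (-0.66, adjusted p = 0.0628), and both lists had an adjusted p = 0.45 with an estimated correlation. Of 5 atrial and skeletal muscle markers Atp2a1 fell by 1.83 (camera adjusted p = 0.291; 2 adjusted over the list alone).

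**Figure D2:**
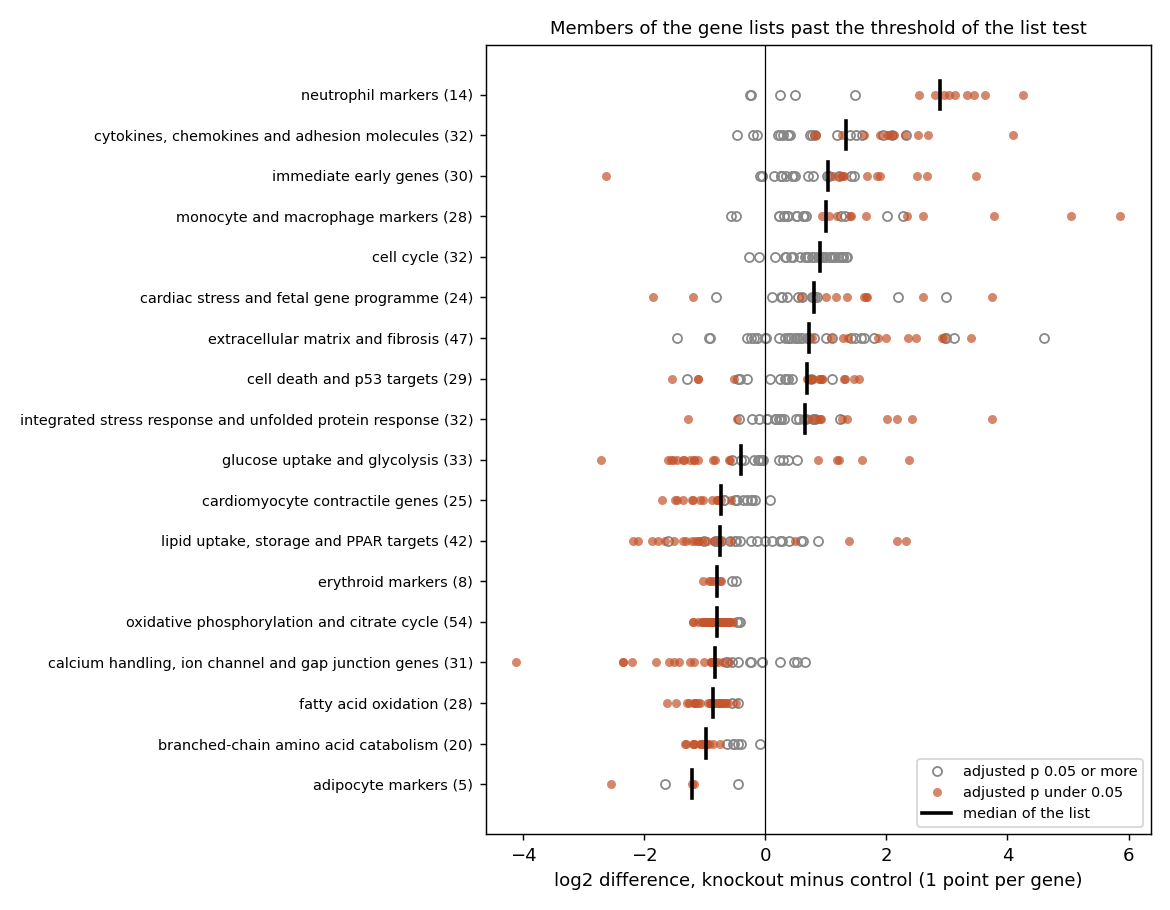
Log2 difference between KO and control hearts (x axis) of each measured member of the 18 lists past the threshold of the list test, 1 point per gene, filled where the gene's adjusted p was under 0.05, with the list's median as a bar and the number of measured members in brackets. Members of oxidative phosphorylation lay together left of 0 (median -0.79), while neutrophil markers reached a median of 2.88.

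The remaining lists did not pass or passed without members. Genes of the p38 pathway went both ways: of 29, 5 rose and 5 fell (median -0.20, mean of the list 0.00215, camera adjusted p = 0.872; 6 and 7 adjusted over the list alone). Map2k3, an activating kinase of p38, rose by 0.91 ± 0.20 (SE, log2) and the downstream genes Hspb1 and Zfp36 by 0.97 and 0.96, though Zfp36 did not pass with normexp (0.38, adjusted p = 0.0682). Mef2c fell by 0.83 ± 0.18. Of 32 cell cycle genes 0 passed singly or adjusted over the list alone, with Ccnd1 at 0.57 (adjusted p = 0.0694, or 0.033 with normexp), although the list as a whole passed (median 0.91, camera adjusted p = 0.00307; adjusted p = 0.592 with an estimated correlation). It did not pass without KO replicate 3 (median 0.59, adjusted p = 0.106), and the median was 0.49 without control replicate 3, 0.55 without control replicate 4, 1.36 without control replicate 2 and 1.46 without KO replicate 2. Of 17 circadian clock genes 7 fell and 3 rose (median -0.25, camera adjusted p = 0.297; 7 and 3 adjusted over the list alone). Per3, Nr1d2 and Tef fell by 1.36, 0.97 and 1.03. Of 33 antioxidant genes 10 rose and 4 fell (median -0.03, mean 0.15, camera adjusted p = 0.241; 12 and 7 adjusted over the list alone). Txnrd1 rose by 1.38 and the regulator Nfe2l2 by 0.84. Of 20 heat shock genes 4 rose and 2 fell (camera adjusted p = 0.243; 4 and 2 adjusted over the list alone). Hsp90aa1 rose by 1.07 and Hspb6 fell by 1.08. Of 27 hypoxia and angiogenesis genes 6 fell and 2 rose (camera adjusted p = 0.772; 8 and 3 adjusted over the list alone). Vegfa fell by 1.09 ± 0.17 and Angpt1 by 1.81 ± 0.32, and Fgf2 rose by 1.25 ± 0.26. Of 29 genes of atrophy, ubiquitin ligases and autophagy 7 fell and 2 rose (camera adjusted p = 0.223; 7 and 2 adjusted over the list alone). Ulk1 fell by 1.44 and Asb2 by 1.64. Of 22 angiotensin, endothelin and natriuretic peptide genes 5 fell and 2 rose (camera adjusted p = 0.337; 6 and 2 adjusted over the list alone). The endothelin receptor gene Ednra fell by 1.04, and the 2 that rose were Edn1 (0.62) and Ednrb (0.59).

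In all, 18 of 32 lists passed, 9 higher and 9 lower in KO, and 0 of 32 with an estimated correlation; fry, which asks whether a list's genes move one way, gave 19. List means per heart gave an exact two-sided permutation p of 0.0286, the smallest that 35 splits allow, for 12 lists including cytokines, neutrophil markers, contractile genes and calcium handling, and after adjustment over the 32 lists the lowest p was 0.0762. For oxidative phosphorylation, fatty acid oxidation, branched-chain amino acid breakdown, macrophage markers and cardiac stress genes this p was 0.0571, since 1 other split parted the hearts as far, and for matrix genes it was 0.114. With no filter on dim probes 22 lists passed, with the antioxidant (0.0252), heat shock (0.0433), lymphocyte (0.0153) and nerve and mesothelial (0.00829) lists among them. The following medians had the same sign within both rows of the slide, of which row 1 held 2 controls and 1 KO heart and row 2 held 2 of each. They were -0.69 and -0.97 for oxidative phosphorylation, -0.58 and -1.12 for fatty acid oxidation and -0.58 and -0.89 for contractile genes. They were 0.50 and 1.43 for macrophage markers, 2.39 and 2.99 for neutrophil markers and 0.26 and 1.42 for matrix genes. The sign differed between rows 1 and 2 for nerve and mesothelial markers (0.56 and -0.04) and interferon genes (-0.45 and 0.16). It also differed for endothelial markers (0.05 and -0.46) and hypoxia and angiogenesis genes (0.07 and -0.14). With slide row as a block 8402 genes passed, and 725 and 1462 passed within row 1 and row 2. Within row 1, where the single KO heart is assumed to vary as the controls do, the fibroblast (median -0.66, adjusted p = 0.00815) and interferon (-0.45, 0.00167) lists passed and the cell cycle list did not pass (0.122). Within row 2 the endothelial list passed (-0.46, 0.0182) and the glycolysis list did not pass (0.106). The median, mean and list test differed in sign for the antioxidant, interferon and p38 pathway lists.

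**Figure D3:**
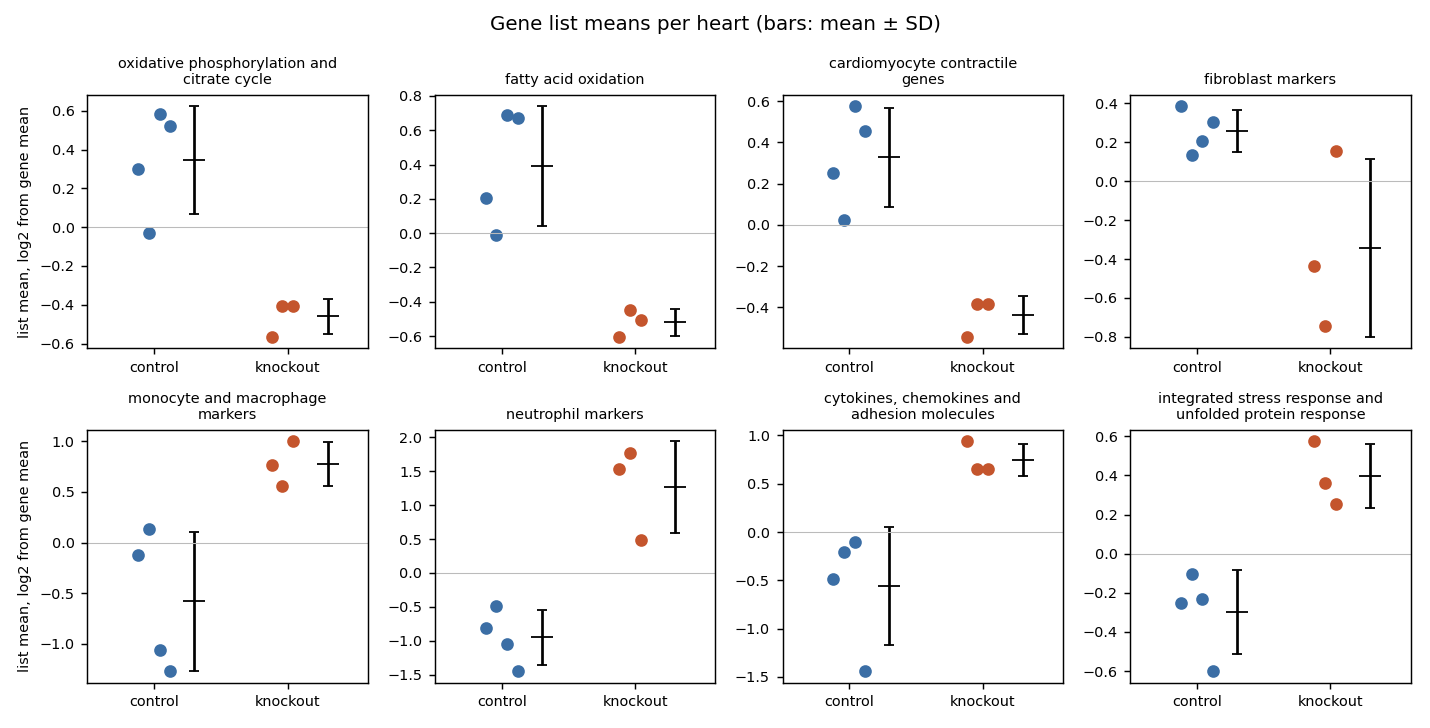
Mean of each list's genes per heart, in log2 units from each gene's mean over all 7 hearts (y axis), for 4 control and 3 KO hearts in 8 lists; the bars show mean ± SD. The 3 KO hearts lay below all controls for oxidative phosphorylation and above all controls for neutrophil and macrophage markers, and for fibroblast markers KO and control values overlapped.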

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

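All tests in this part except the counts of 2-fold genes and of lists over other splits were chosen after the result was seen. Of 191 gene values and list means examined in the 4 controls, 5 had 1 heart far from the other 3, fewer than the 1 in 20 that chance gives. Control 2 was apart for Dld (4.49, the others from 5.18 to 5.24), Tcap (8.82, the others from 9.50 to 9.51) and Mmp9 (-5.06, the others from -6.09 to -5.93, none well above background), in log2 relative to the 75th percentile. Control 4 was apart for Slc3a2 (3.30, the others from 3.63 to 3.68) and for the Y-linked gene Uty (-0.51, the others from -3.37 to -3.07), while a second Uty probe read -3.34 in control 4.

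Chance was made unlikely, though not excluded, for the number of changed genes. Of the 35 splits of the 7 hearts into 4 and 3, 1, the real one, gave as many as 5640 genes. That share, 2.86%, is the smallest that 35 splits allow, and the highest of the other splits gave 3953. For genes changed at least 2-fold 1 of 35 splits, again the real one, gave 2302, and the next gave 1794. The next split set control 1, 3 and 4 against control 2 with the KO hearts, which points to a structure of the samples in which control 2 lay nearest to the KO hearts. For the number of lists chance cannot be excluded: 5 of 35 splits gave at least 18 lists past the threshold, and the highest of the others gave 19.

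Liver transcripts were present in the controls and lower in the KO hearts. Of 25 measured hepatocyte markers, a list chosen after seeing the data, 19 fell and 0 rose, and 12 were not well above background on any KO array. Their median was -2.62, or -1.65 with bounds (camera adjusted p = 7.68e-12, 0.17 with an estimated correlation). The adjustment was over the 4 lists chosen after seeing the data only. Position on the slide is argued against, since the median was -2.70 and -2.88 within rows 1 and 2. Liver RNA in the control hearts and an effect of genotype on these genes cannot be told apart. A single source would keep its transcripts in 1 ratio, and 24 of the 25 markers were lowest in the same heart, control 2, a count that replaced a correlation over the 4 controls after that had been computed. Yet of 870 other genes that fell at least 2-fold in KO 76.1% were lowest in control 2 too, and random lists of 25 of them shared their lowest control in 22 at the 95th percentile. The number sharing their highest control, 18, equalled the 95th percentile of such lists. For the markers that heart was control 1, while 13.9% of the 870 other genes were highest in control 1, so the markers differed from them in this. The marker mean was -0.73, -2.22, -1.17 and -1.32 in controls 1 to 4 against -4.06 to -3.76 in KO. Both explanations stay open, and without the markers 5620 genes passed.

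Of 54 genes of oxidative phosphorylation and the citrate cycle 51 fell in KO, and of 28 monocyte and macrophage markers 11 rose and 17 did not pass. Both lists had a camera adjusted p of 0.45 with an estimated correlation and an exact permutation p of 0.0571. If a lower share of cardiomyocytes raised the markers of all other cell types alike, the fibroblast and macrophage lists would rise together. The fibroblast list mean changed by 1.95 less than the macrophage list mean (-1.95 ± 0.38 SE, log2, exact permutation p = 0.0286, the smallest that 35 splits allow). The means of these lists thus did not rise together. Whether cell shares shifted evenly cannot be told from this, since the level of a marker per cell can change. Entry of immune cells stays open, and since it would also lower the share of cardiomyocytes, a lower share is not excluded. The choice of scaling between the arrays did not remove the pattern. Under 5 other scalings the oxidative phosphorylation median stayed at -0.67 or lower and the macrophage median at 0.95 or higher. These scalings moved the median of all genes by at most 0.09, so a scaling error common to all of them stays open. Position on the slide is argued against for oxidative phosphorylation, with a median of -0.69 in the row where it was nearer 0. Macrophage medians were 0.50 in row 1 and 1.43 in row 2, so a part played by position stays open for them. Deletion of Mapk14 and presence of the Cre transgene cannot be told apart by this design, and both stay open as untested explanations.

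Controls 1 and 2 lay apart from controls 3 and 4 in the first principal component (-32.2 and -3.53 against -70.4 and -77.2, KO hearts from 41.0 to 78.3; 66.8% of the variance). These pairs lie in different rows of the slide. If position were the cause, KO 1 would differ from KO 2 and 3 in the same way; the slope over 22302 genes, which are not independent, was 0.228, and with 1 KO heart in row 1 position and differences between animals cannot be told apart. The bound below which this slope would argue against position was lowered to 0 after its value was seen, since a single KO heart gives it no spread; under the bound first written it would have argued against position. Across genes, the difference of controls 1 and 2 from controls 3 and 4 correlated at 0.605 with the KO minus control difference. For KO 1 against KO 2 and 3 this correlation was 0.466. Variation within each group thus ran partly along the same genes as the difference between the groups. No biological explanation was tested.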

How the results depend on the processing

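The settings within a slide row, with a percentile over detected probes and without hepatocyte markers were chosen after seeing the data. Signal over background limits genes detected in 1 group to a bound. Of 153 named genes (128 called), 148 to 152 kept direction and side of the threshold under normexp, quantile normalization, median centring, the percentile over detected probes and the authors' value table. The median of all genes moved by at most 0.09 and the share of higher calls from 40.5% to at most 46.2% under these scalings, and 17 or 18 lists passed. The cause of the moves below was not tested, except that fewer hearts, more features or a stricter test were part of the setting. Normexp also added an offset of 50 to every spot, which draws dim signals together by construction. Smaller folds of dim genes with normexp, and bounds not met, follow at least in part from that.

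With normexp 1364 genes changed at least 2-fold, and dim genes lay nearer 0: of 99 called genes outside the largest changes 12 were smaller by over 1.5 times, such as Fosl1 (1.53), Mthfd2 (1.46), Il1b (1.05), Krt19 (0.96), Acad8 (-0.70), Pmaip1 (0.68), Per3 (-0.64) and Fgf2 (0.48), each still called. Esr1 was 3.93. Every bound given as at least N-fold lay above the fold with normexp, an outcome that the offset favours by construction. Car3 (-0.66) and Zfp36 (0.38) lost their call with normexp, and 3 named genes gained one, Ccnd1 (0.59) and Psmb8 (0.50) among them. With no filter 1415 genes passed (440 higher, 975 lower; 1146 at least 2-fold), with 49 named genes no longer called and 22 lists passed, 4 of them gained. With array weights, which gave KO 1 a weight of 6.53 against 0.455 to 1.70, 11999 passed (5360 and 6639; 3510). With an unmoderated test 90 passed (25 and 65; 41). At 0.1 8731 passed, 3802 higher. With slide row as a block 3585 were higher. Within slide row 1 725 passed (246 and 479; 725), within row 2 1462 (694 and 768; 1426), and Esr1 at 8.23 did not pass there. Esr1 at 7.11 did not pass the unmoderated test either. Camera with an estimated correlation gave 0 lists and fry in either direction 30.

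Leaving out each heart gave 69 to 6970 genes (20 to 2842 higher, 49 to 4128 lower, 69 to 3182 at least 2-fold), lowest without KO replicate 1 and highest without control replicate 2, and 17 to 19 lists. Without KO replicate 1 120 of the 128 called genes lost their call, without KO replicate 2 59 and without KO replicate 3 7.

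The replicate numbers do not pair the hearts: deviations of same-numbered hearts correlated at 0.184, -0.223 and -0.197 across genes. With the replicate block 9 genes passed (6 and 3; 9), Esr1 at 7.11 did not, and 19 lists passed.

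Reversed were genes without a call, and Pmaip1. Pmaip1 was -0.73 in the authors' value table and did not pass there (adjusted p = 0.811). Ddx3y was -0.0318 with array weights, -0.0336 with slide row as a block, -0.144 within row 2 and -0.110 to 0.139 with each heart left out. Mapk13 was -0.605 to 0.15 with each heart left out, and Mapk12 was -0.0233 within row 2.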

Other observations

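All lists in this part were chosen after seeing the data, so their p values are no independent support. They were adjusted over the 4 lists so chosen, so the adjusted p values cannot be set against those of the fixed lists. Before adjustment, camera with an estimated correlation gave p = 0.127 for ribosome assembly and 0.18 for the mitochondrial ribosome. For the fixed list of oxidative phosphorylation it gave 0.187. Among genes that passed, those that build ribosomes rose in KO and those of the mitochondrial ribosome fell, while 10 and 37 did not pass. Adjusted over the mitochondrial list alone 52 fell and 1 rose. Of 43 measured genes of nucleolar ribosome assembly 33 rose and 0 fell (median 0.95, camera adjusted p = 2.20e-15, 0.17 with an estimated correlation). The RNA helicase gene Ddx21 rose by 1.53 ± 0.27 (SE, log2, adjusted p = 0.0139), the snoRNP gene Nop58 by 1.41 ± 0.25 and Nolc1 by 1.24 ± 0.19. Of 77 mitochondrial ribosomal protein genes 40 fell and 0 rose (median -0.48, camera adjusted p = 2.58e-11, 0.18 with an estimated correlation), Mrpl34 by 1.19 and Mrps35 by 1.09.

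The Iroquois homeobox genes, transcription factors that pattern the ventricle and its repolarisation, fell together. All 5 measured members fell (median -0.91, camera adjusted p = 0.00101, 0.17 with an estimated correlation): Irx3 by 1.13 ± 0.13, Irx4 by 1.20 ± 0.27, Irx5 by 0.91 ± 0.18, Irx2 by 0.90 and Irx1 by 0.69 (SE, log2). Medians within slide rows 1 and 2 were -1.01 and -0.997.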
